A study of Equus caballus with 17 samples.

How the data were processed

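Gene counts were analysed for 17 RNA-seq libraries of cultured horse skeletal muscle cells in 5 groups set by oxygen level and time, as the labels give them. The deposited values are whole-number counts of reads per Ensembl gene ID, 1 table per library. Per the submitters' processing notes, bcl2fastq 2.20, fastp 0.23.2, FastQC 0.11.5, MultiQC 1.14, STAR 2.7.10a, HTSeq 0.13.5, R 4.2.2, DESeq2 1.38.0 and the horse genome build EquCab3.0 were used, and the role of each tool is not given there. Per the labels' protocols, the libraries were sequenced as paired-end reads on an Illumina NovaSeq. The annotation release, the strand setting and the rule for reads that map to several places are not given in the sources used here, so counts of genes with near-identical copies, overlapping genes or antisense partners are uncertain. Each table holds 38849 gene IDs, and the totals per library, from 12358247 to 24274627, cover counted reads only.

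The files do not pair the IDs with gene names, and the reference table of 39335 genes used for names pairs none of them with an Ensembl ID, so 0 IDs matched a symbol. The 29 gene lists, the panel of single genes and the tests of gene sets that were fixed before the data were examined work on symbols and were not run. The rule for named genes, also fixed then, takes genes with a symbol. In its place, the 2 largest rises and 2 largest falls in log2 fold change are printed by ID for 1% against 21% O2 at 72 h, from genes that met the same conditions: adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between libraries. Those conditions were met by 44 higher and 93 lower genes. Gene positions are not used here.

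Differential expression was tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test on the deposited counts, with TMM scaling, in 1 fit of all 17 libraries with a mean per group. After the low-count filter (filterByExpr) 14465 of 25530 genes with a count were tested. The common biological coefficient of variation was 25.1%. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Fold changes carry the standard error implied by the test statistic. Log2 CPM used a prior count of 2. Differences between libraries are medians over 9921 genes with a mean of at least 100 counts, and whole profiles were compared by exact permutation tests of the mean difference between groups less that within them. Chi-square tests of library pairs used genes with at least 10 counts over the pair.

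The edgeR fit was tested on simulated counts with the means, spread and library sizes of the data and 200 changed genes. It found 67%, 60%, 31%, 40%, 64% and 29% of the genes changed by 2-fold, and 94%, 91%, 90%, 88%, 94% and 82% of those changed by 4-fold. These are for 1% against 21% O2 at 48 h, 3% against 21%, 1% against 21% and 1% against 3% O2 at 72 h, and 72 h against 48 h at 21% and at 1% O2. False calls numbered 7 or 8 per comparison. Genes were drawn independently, without the grouping of libraries seen in the data. The changed genes all had a mean over 1 CPM, so the 1847 tested genes under 1 CPM are not covered by these percentages. Correlations between comparisons that share libraries were set beside 20 simulations of unchanged groups.

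The titles number the libraries within each group. Same-numbered libraries deviated together at 48 h between 1% and 21% O2 (r = 0.49, 0.13 and 0.71 across genes for numbers 1, 2 and 3), each above a minimum of 0.1. There the numbers were taken as pairs, by the data and not by a statement in the labels. For number 2 the link was weak, as replicate 2 at 1% O2 went best with another number at 21% O2. A block by number left 0 genes in that comparison.

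Alternatives fixed before the data were examined were DESeq2 size factors, library size only, no low-count filter, a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), robust empirical Bayes, the groups compared alone, a replicate block, a test against a fold of 1.5 and each library left out in turn. Alternatives chosen after seeing the data were 1, 2 and 3 surrogate variables (sva 3.50.0, which estimated 3), the block with the groups compared alone, adjusted p thresholds of 0.04 and 0.06, and leaving out the 3 libraries opposite to their group on the first principal component.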

Results

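RNA was sequenced from cultured cells of horse skeletal muscle that had been kept at different oxygen levels. The cells came from the gluteus medius of 1 foal and were pre-plated to lower the share of fibroblasts, which leaves a culture rich in myoblasts, the precursors of muscle fibres. The 17 libraries fell into 5 groups by oxygen level and time. At 48 h, 5 libraries came from cells at 21% O2, the level of room air, and 3 from cells at 1% O2. At 72 h, 4 libraries came from cells at 21% O2, 3 from cells at 3% O2 and 2 from cells at 1% O2. The labels speak of 3 technical replicates per group, where the groups here hold 2 to 5 libraries, so p-values here measure only the spread between these samples. Total counts per library ran from 12358247 to 24274627. They averaged 19217185 ± 3880076 at 21% O2 for 48 h (SD, n = 5), 15939230 ± 2554965 at 1% O2 for 48 h (SD, n = 3), 17350418 ± 4446905 at 21% O2 for 72 h (SD, n = 4), 16072688 ± 3316396 at 3% O2 for 72 h (SD, n = 3) and 15616619 ± 1258178 at 1% O2 for 72 h (SD, n = 2). Genes are known here by Ensembl IDs that the files do not pair with names, so the comparisons are given as numbers of genes, with 4 IDs as examples.

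The oxygen and time groups were not cleanly separated across the transcriptome. The first principal component of log2 CPM (read counts scaled to a common library total) held 45.0% of the variance and the second 15.8%. All 4 libraries at 21% O2 for 72 h lay on one side of the first component, at 39.2 to 44.8, and both libraries at 1% O2 for 72 h on the other, at -41.8 and -18.9. In each of the other groups 1 library lay opposite to the rest: replicate 3 at 21% O2 for 48 h (34.9), replicate 3 at 1% O2 for 48 h (32.5) and replicate 1 at 3% O2 for 72 h (-44.5). The 5 groups held 38.0% of the variance, against a mean of 25.0% over 100000 permutations of the labels (permutation test, one-sided p = 0.0403).

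**Figure D1:**
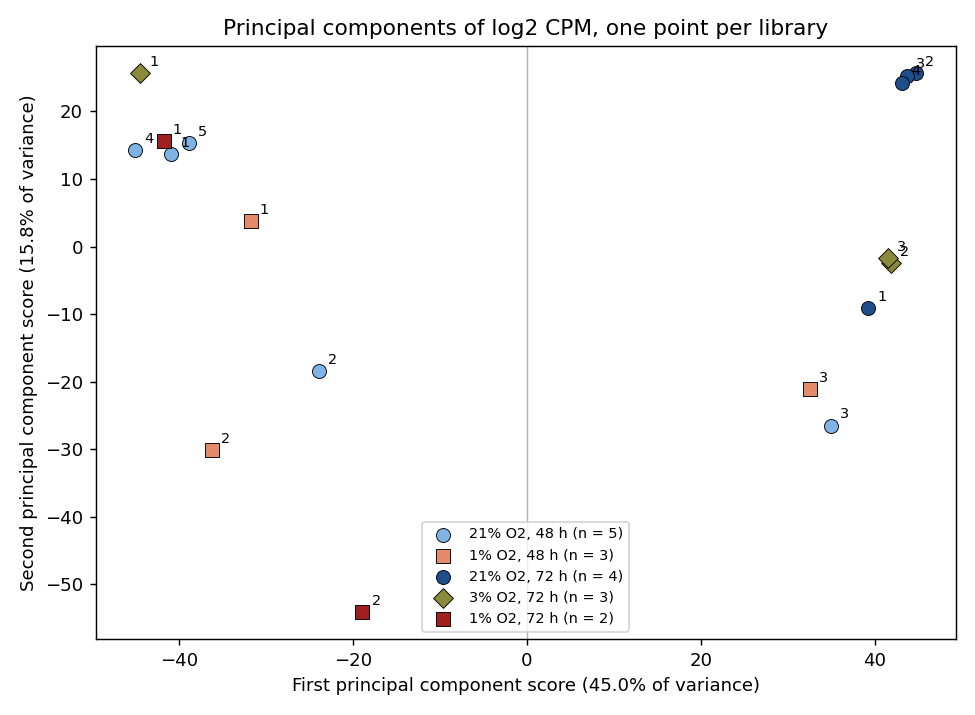
First and second principal component scores of log2 CPM for the 17 libraries, 1 point each, with colour and shape for the group and the replicate number beside the point. Libraries at 21% O2 for 72 h lie at 39.2 to 44.8 on the horizontal axis, and 1 library of each of 3 other groups lies on the opposite side from the rest of its group.

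The library most like a given one belonged to its own group for 7 of 17 libraries, where permuted labels gave a mean of 2.88 (permutation test, one-sided p = 0.0425). In this test and in that of the variance above, labels were permuted freely over the 17 libraries, without regard to the replicate numbers. For the other 10 it belonged to another oxygen level or time. Replicate 1 at 1% O2 and replicate 1 at 21% O2, both at 48 h, differed by a median of 0.097 in log2 CPM. At 48 h, replicate 3 at 1% O2 and replicate 3 at 21% O2 differed by 0.118. Replicate 1 at 1% O2 for 72 h lay 0.126 from replicate 4 at 21% O2 for 48 h, but 0.332 from the other library of its own group. The closest pair of all, replicates 2 and 3 at 3% O2 for 72 h, differed by 0.0736. Their counts still differed by more than sampling noise, with a chi-square of 2.29 per degree of freedom, so they were not treated as copies of 1 library. Separate preparations from the same culture would also differ by more than that noise.

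**Figure D2:**
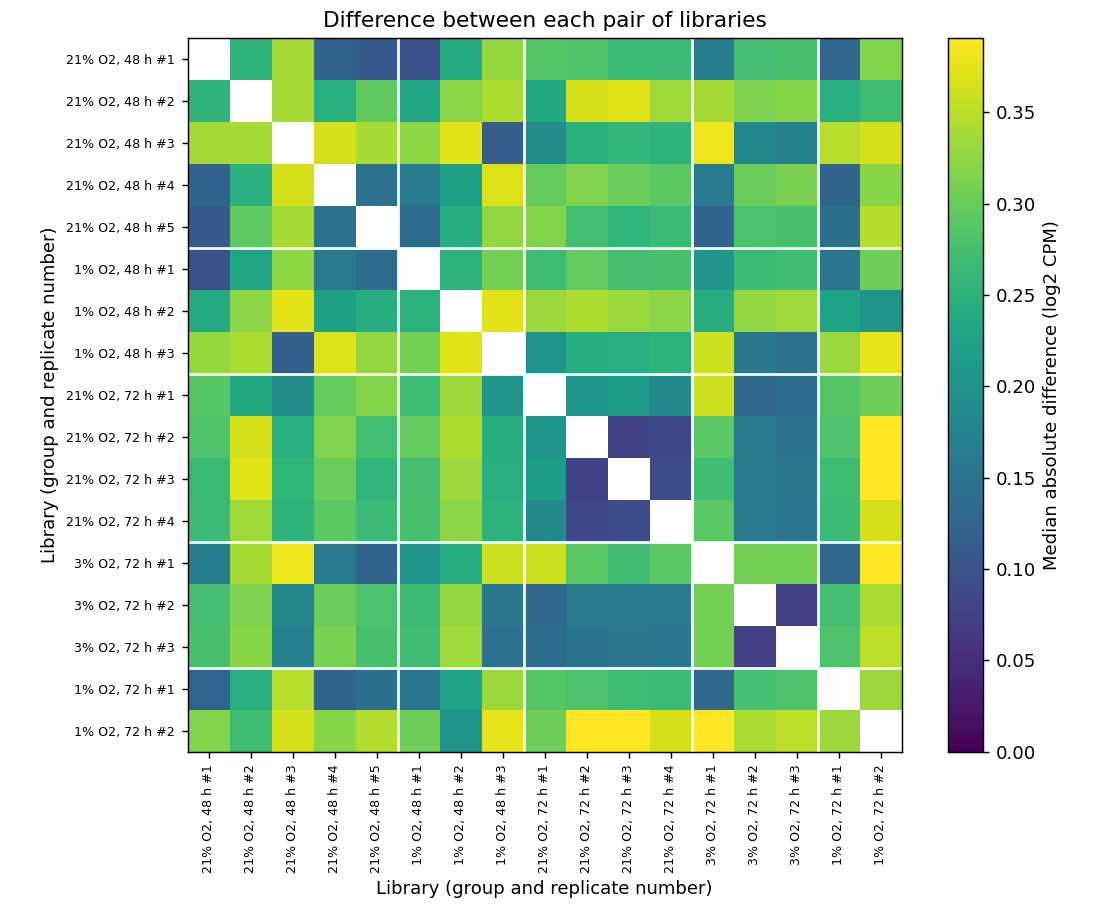
Median absolute difference in log2 CPM between each pair of the 17 libraries, with darker colours for smaller differences and white lines between groups. Dark cells off the diagonal blocks mark libraries that lie close to another group, such as replicate 3 at 1% O2 and replicate 3 at 21% O2 at 48 h, which differed by 0.118.

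The comparison of 1% with 21% O2 at 48 h asked how the cells responded to severe hypoxia at the shorter time. None of the 14465 genes tested passed the threshold between the 3 libraries at 1% O2 and the 5 at 21% O2. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment gave 0 genes, with a smallest adjusted p of 1.00. At an unadjusted p under 0.05 there were 422 genes, where 723 were expected by chance, and DESeq2 and limma-voom each gave 0. Groups without overlap were seen for 1.55% of genes, against 3.57% by chance. Between the groups, libraries differed by a mean of 0.256 ± 0.0938 in log2 CPM (SD), against 0.269 within them (exact permutation test over 56 splits, one-sided p = 0.696). With labels exchanged only within the 3 pairs of equal replicate number, the exact one-sided permutation p was 0.625, where 8 splits allow no less than 0.125. In simulated counts of this design the test found 67% of genes changed by 2-fold and 94% of those changed by 4-fold. The changed genes all had a mean over 1 CPM, and the simulation held none of the grouping of libraries seen here.

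At 72 h, 3% O2 was compared with 21% O2 to measure the response to moderate hypoxia. No gene passed the edgeR test between the 3 libraries at 3% O2 and the 4 at 21% O2. The unadjusted p was under 0.05 for 794 genes, against 723 expected, while DESeq2 gave 5 genes, all lower at 3% O2, and limma-voom gave 0. Groups without overlap were seen for 10.8% of genes, against 5.71% by chance. The mean difference between libraries of the groups was 0.202 ± 0.0781 in log2 CPM (SD), and 0.173 within them (exact permutation test over 35 splits, one-sided p = 0.2). Without replicate 1 at 21% O2 for 72 h, 27 genes passed, and with 3 surrogate variables, added after the data were seen, 91.

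The comparison of 1% with 21% O2 at 72 h, which measured the response to severe hypoxia at the longer time, gave more genes than the others between oxygen levels. With 2 libraries at 1% O2 and 4 at 21% O2, 50 genes were higher and 127 lower at 1% O2, a total of 177 genes by edgeR with adjusted p under 0.05. The higher genes had a median log2 fold change of 1.02 and the lower genes one of -1.94. Among them, 26 rose and 110 fell by at least 2-fold. By mean level, 15 of the fallen genes lay under 1 CPM, 48 at 1 to 10, 57 at 10 to 100 and 7 above 100 CPM, where 1847, 3733, 7014 and 1871 genes were tested. Of the risen genes, 19 were above 100 CPM. Over all genes tested, 36.3% showed no overlap between the groups, against 13.3% by chance.

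Every one of the 177 genes lay just under the threshold, with edgeR adjusted p between 0.0469 and 0.0497, so that 0 genes passed at 0.04 and 318 at 0.06. The number ran from 0 without replicate 2 at 1% O2, or without replicate 2, 3 or 4 at 21% O2, to 547 without replicate 1 at 1% O2 and 599 without replicate 1 at 21% O2. Other fits gave 0 genes (limma-voom), 0 against a fold of 1.5 (glmTreat), 986 (DESeq2) and 1705 (edgeR on these 2 groups alone), and scaling by library size alone gave 33 higher and 287 lower genes. With 1, 2 and 3 surrogate variables, added after the data were seen, the number was 1056, 484 and 0. For the whole profile, the mean difference between libraries of the groups was 0.319 ± 0.0541 (SD), against 0.171 within them, and the exact one-sided permutation p was 0.0667, the smallest that 15 splits allow.

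**Figure D3:**
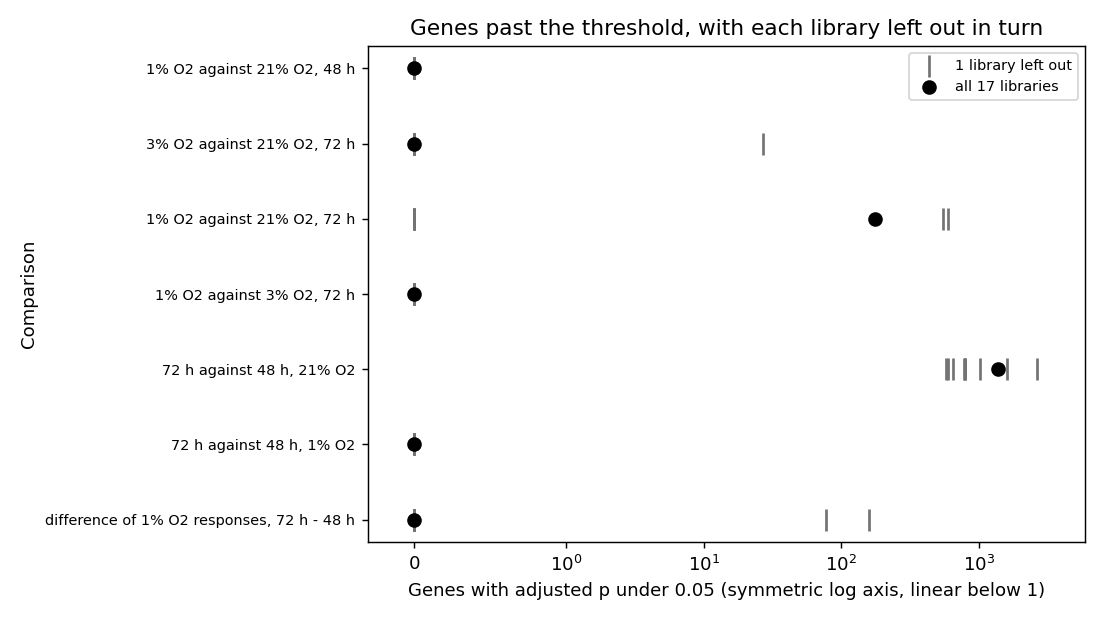
Number of genes with edgeR adjusted p under 0.05 in each comparison, on a symmetric log axis, with all 17 libraries (black points) and with each library of the groups compared left out in turn (grey bars). For 1% against 21% O2 at 72 h the number moved from 177 to between 0 and 599, and for 72 h against 48 h at 21% O2 from 1392 to between 578 and 2674.

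Among genes past the threshold with at least 5 CPM in the higher group and no overlap between libraries, the largest rise at 1% O2 for 72 h was that of ENSECAG00000013981, from 2.62 ± 1.40 CPM at 21% O2 (SD, n = 4) to 12.0 ± 7.54 CPM at 1% O2 (SD, n = 2). Its log2 fold change was 2.21 ± 0.48 (SE, edgeR adjusted p = 0.0469). ENSECAG00000001246 rose from 1.33 ± 0.585 to 5.92 ± 0.0852 CPM in the same groups, a log2 fold change of 2.17 ± 0.49 (SE, edgeR adjusted p = 0.0469). The largest fall under the same conditions was that of ENSECAG00000015516, from 9.31 ± 4.08 CPM at 21% O2 (SD, n = 4) to 0.396 ± 0.351 CPM at 1% O2 (SD, n = 2), a log2 fold change of -4.47 ± 0.97 (SE, edgeR adjusted p = 0.0469). ENSECAG00000022875 fell from 10.8 ± 2.81 to 0.478 ± 0.153 CPM, a log2 fold change of -4.46 ± 1.04 (SE, edgeR adjusted p = 0.0493). At 3% O2 for 72 h the means lay between these: 4.75 ± 0.938, 3.11 ± 1.67, 2.62 ± 1.57 and 5.56 ± 4.16 CPM in the same order (SD, n = 3), and none of the 4 differed from 21% O2 there by edgeR (adjusted p from 0.796 to 0.952). For 3 of them replicate 1 at 3% O2, the library opposite to its group on the first component, lay apart from replicates 2 and 3: 5.02 against 1.95 and 2.35 CPM for ENSECAG00000001246, 0.82 against 3.34 and 3.70 CPM for ENSECAG00000015516, and 0.769 against 8.22 and 7.69 CPM for ENSECAG00000022875. At 21% O2 for 48 h the means of the 4 genes, in order, were 9.57 ± 3.53, 4.57 ± 2.87, 0.693 ± 0.587 and 1.82 ± 1.37 CPM (SD, n = 5). All 4 changed with time at 21% O2 by edgeR (adjusted p from 0.00208 to 0.0157), each in the opposite direction. None passed the threshold with time at 1% O2 by edgeR. The log2 fold changes there, in order, were 0.64 ± 0.51, 0.42 ± 0.51, -0.94 ± 1.02 and -2.57 ± 1.04 (SE). The 21% O2 libraries at 72 h enter the comparison with 1% O2 and that with 48 h, with opposite signs. The 4 genes were picked for large differences in the first, which makes opposite directions in the second common. These directions therefore do not by themselves tie the differences at 72 h to a shift at 21% O2 with time. All 4 kept their direction under the alternatives tried, and each lost its call under at least 10 of 21. The log2 fold change of ENSECAG00000013981 was 1.37 without replicate 2 at 1% O2, and with 3 surrogate variables those of the 4 genes were 0.81, 1.24, -1.997 and -2.39 in the order given.

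**Figure D4:**
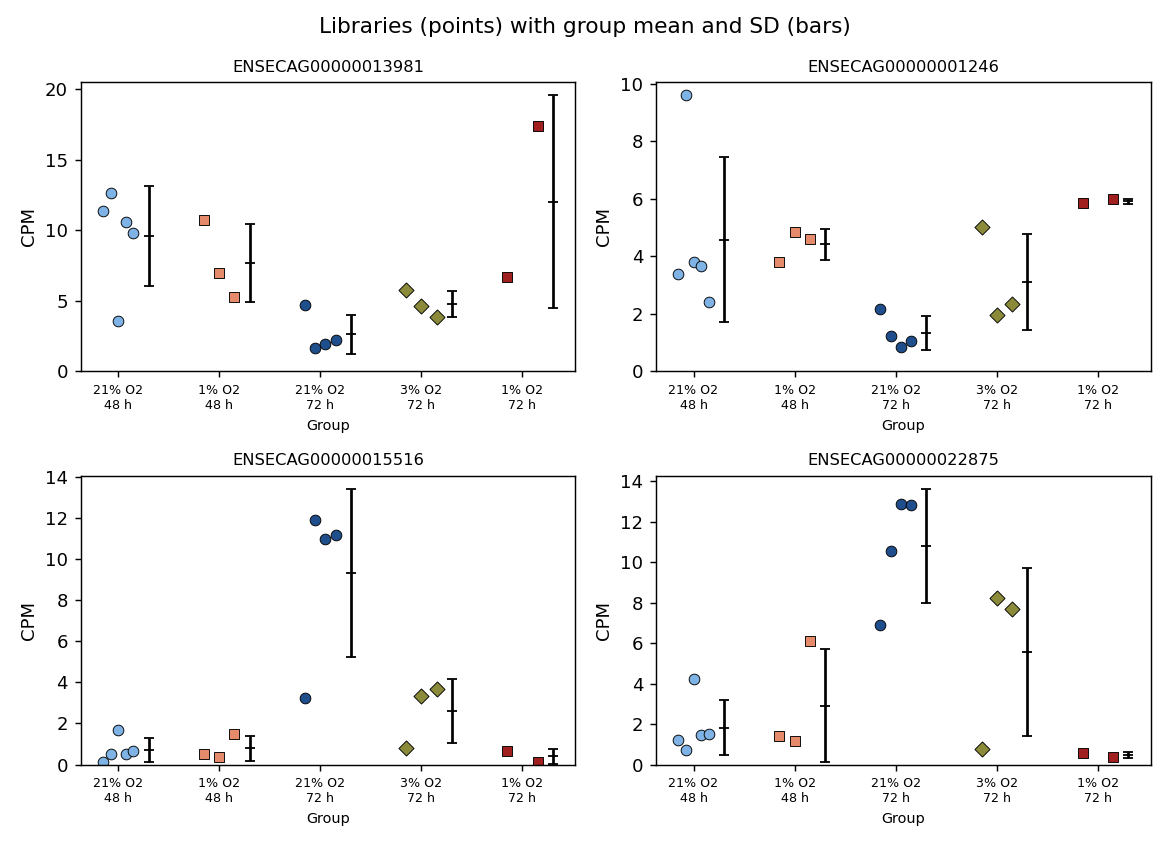
CPM of the 4 example genes in each library (points) by group, with the group mean and SD as bars. The upper genes were lowest at 21% O2 for 72 h (means of 2.62 and 1.33 CPM) and the lower genes highest there (9.31 and 10.8 CPM).

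The lower oxygen levels were also compared with each other at 72 h. No gene passed the edgeR test between 2 libraries at 1% O2 and 3 at 3% O2, 1265 genes had an unadjusted p under 0.05 against 723 expected, and DESeq2 and limma-voom gave 0. Groups without overlap were seen for 22.3% of genes, against 20% by chance. Without the 3 libraries opposite to their group on the first component, picked by their expression after the data were seen, 1411 genes passed, with p-values that this choice makes too small. Of the 3, only replicate 1 at 3% O2 belongs to this comparison, and leaving it out alone gave 0 genes. The fold changes of 3% and of 1% O2 against 21% O2 correlated across genes (Pearson r = 0.61, Spearman rho = 0.56), where genes are not independent replicates. Both use the same 4 control libraries, which alone gave r = 0.36 in simulated unchanged groups. With the controls split into separate pairs, r was 0.41 to 0.51 over 6 splits. The covariance was 0.182, against 0.0585 simulated. The simulation held none of the grouping of libraries seen here, and a shift common to the control libraries stays in both pairs. The excess over the simulation therefore does not show a response common to 3% and 1% O2. Without replicate 1 at 3% O2, r fell to 0.29.

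Time in culture at 21% O2 gave the largest number of genes. From 48 h (5 libraries) to 72 h (4 libraries), 936 genes rose and 456 fell, 1392 genes in all by edgeR with adjusted p under 0.05. The risen genes had a median log2 fold change of 1.35 and the fallen genes one of -0.78. At least 2-fold changes were seen for 595 risen and 140 fallen genes, and 288 genes passed a test against a fold of 1.5. DESeq2 gave 1965 genes, limma-voom 1583, and library size scaling 1209 higher and 292 lower genes. Of the settings added after the data were seen, 1, 2 and 3 surrogate variables gave 2288, 3350 and 1288 genes, and leaving out the 3 libraries opposite to their group on the first component, which makes p-values too small, gave 4068. Groups without overlap were seen for 13.8% of genes, against 1.59% by chance. The whole profiles differed by a mean of 0.284 ± 0.0430 in log2 CPM between groups (SD) and 0.214 within them (exact permutation test over 126 splits, one-sided p = 0.0238, adjusted over the 6 comparisons 0.143).

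The number of time genes moved by over 1.5 times when any of 7 libraries was left out. It was 2674 without replicate 3 at 48 h, and 786, 795 and 791 without replicates 1, 4 and 5 at 48 h. Without replicates 2, 3 and 4 at 72 h it was 578, 595 and 650.

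The same comparison of times at 1% O2 showed no gene by edgeR between 2 libraries at 72 h and 3 at 48 h. In simulated counts, without the grouping of libraries seen here, the test found 29% of genes changed by 2-fold, against 64% at 21% O2. The absence of calls thus does not show that time had no effect at 1% O2. At an unadjusted p under 0.05 there were 258 genes, against 723 expected, and DESeq2 and limma-voom gave 0. Groups without overlap were seen for 8.13% of genes, against 20% by chance. Among the 936 genes that rose with time at 21% O2, 332 had a positive fold change with time at 1% O2, and among the 456 that fell, 229 had a negative one. These comparisons share no library. The mean difference between libraries of the groups was 0.266 ± 0.0852 (SD), against 0.316 within them (exact permutation test over 10 splits, one-sided p = 0.9, smallest possible 0.1).

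Whether the response to 1% O2 differed between 72 h and 48 h was tested as an interaction. By edgeR 0 genes passed, with a smallest adjusted p of 0.163, while 2020 genes had an unadjusted p under 0.05 against 723 expected. DESeq2 gave 245 genes and limma-voom 0, and edgeR on the groups compared alone gave 8. Of the settings added after the data were seen, 1 and 2 surrogate variables gave 48 and 5 genes and 3 gave 0, and leaving out the 3 libraries opposite to their group on the first component gave 713. The number by edgeR was 159 without replicate 3 at 21% O2 for 48 h and 77 without replicate 1 at 21% O2 for 72 h. The fold changes of 1% against 21% O2 at the 2 times, which share no library, had r = -0.07 (Spearman rho = -0.08) across genes. That correlation was -0.39 without replicate 2 at 1% O2 for 48 h, 0.38 without replicate 3 there, -0.32 without replicate 2 at 1% O2 for 72 h and -0.31 without replicate 3 at 21% O2 for 48 h.

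Of the 177 genes that differed between 1% and 21% O2 at 72 h, 164 also changed with time at 21% O2, all in the opposite direction. There were 123 genes lower at 1% O2 and higher with time, where independent lists would share 8.22, and 41 higher at 1% O2 and lower with time, where they would share 1.58. The libraries at 21% O2 for 72 h enter both comparisons with opposite signs, which by itself makes opposite directions common, and the numbers for independent lists leave this out. Across genes the fold changes had r = -0.82, against -0.42 in simulated unchanged groups and -0.76 to -0.67 with the shared libraries split into separate pairs. The covariance was -0.429, against -0.0581 simulated. The simulation held none of the grouping of libraries seen here. A shift common to the shared libraries stays in both pairs when they are split. The excess over the simulation therefore does not separate oxygen or time from such a shift. At 48 h, where no library is shared, 43 of the 127 lower genes and 31 of the 50 higher genes had the same sign of fold change for 1% against 21% O2.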

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

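Groups of 4 and 5 libraries were examined for 1 value far from the rest, by the gap to the nearest value over the range of the group. Chance alone gives about 1 in 20, and 5 of 18 groups of values showed one. The 18 reuse the same libraries and include the 4 printed genes, which were picked for large changes. They are not independent, so 5 of 18 is no measure of an excess over chance. The tests of explanations below, with the counts over other splits, were all chosen after the grouping of libraries had been seen. All of them were run before their predictions were written.

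On the first principal component, replicate 3 at 21% O2 for 48 h had a score of 34.9, while the other 4 libraries lay between -45.1 and -23.9. On the second, replicate 1 at 21% O2 for 72 h had a score of -9.12, and the others 24.3 to 25.7. The level of ENSECAG00000001246 was 9.61 CPM in replicate 2 at 21% O2 for 48 h, against 2.40 to 3.81 in the others. ENSECAG00000022875 had 4.21 CPM in replicate 3 at 21% O2 for 48 h, against 0.712 to 1.496. ENSECAG00000015516 had 3.22 CPM in replicate 1 at 21% O2 for 72 h, against 11.0 to 11.9.

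The first pattern is that 10 libraries lay closest to a library of another group, and depth is argued against, as all 10 still lay closest to another group in each of 20 thinnings to 1 total. A batch marked by the same number in every group is argued against by correlations as low as -0.308 between same-numbered libraries, although numbers did go together at 48 h. The best single exchange of 2 labels left 1 of the 3 displaced libraries, with 2 exchanges tied, so wrong labels stay open, since 1 exchange moves only 2 libraries. A few genes taking most of the counts is argued against for 9 of the 10 libraries. By ranks within each library, without the 73 genes among the 50 highest of any, these 9 still lay closest to another group. For the remaining library it stays open. Differences between flasks or cell states that the labels do not name also stay open and were not tested.

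The second pattern is the set of 177 genes for 1% against 21% O2 at 72 h. An axis of variation that the labels do not name is a candidate explanation, since libraries outside the comparison deviated from their own groups along these fold changes with a median absolute correlation of 0.507 (11 libraries, 0.115 to 0.875), and deviations within 1 group are not independent. Surrogate variables do not settle it: 177, 144 and 0 of the genes remained with 1, 2 and 3 of them. In a fit of these groups alone, 1 of 15 splits gave as many genes as the real 1705, the highest other split gave 44, and 15 splits are too few for a share under 0.05. Oxygen and the axis cannot be told apart for these genes, because both libraries at 1% O2 lie on one side of the first component and all 4 at 21% O2 on the other.

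The third pattern is the set of 1392 genes that changed with time at 21% O2. In a fit of these groups alone, 2 of 100 splits, drawn from 126, gave as many genes as the real 2008. That share is not adjusted over the comparisons whose splits were counted. The whole-profile test missed the threshold after adjustment (exact permutation test, adjusted p = 0.143), so chance is not excluded. The other of the 2 splits gave 4443 by placing replicate 3 at 48 h with the 72 h libraries, which points to a structure of the samples. An axis that the labels do not name may contribute: the median absolute correlation was 0.724 over 6 libraries outside the comparison (0.291 to 0.844), and 1372, 1390 and 684 of the genes remained with 1, 2 and 3 surrogate variables. Time in culture and such an axis cannot be told apart here, as the libraries of the 2 times lie mostly on opposite sides of the first component.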

How the results depend on the processing

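Settings chosen after the data were seen were 1, 2 and 3 surrogate variables, thresholds of 0.04 and 0.06, the block with the groups compared alone, and leaving out the 3 displaced libraries. The last picks libraries by their expression, which tightens the groups and makes p-values too small. The cause of each change was not tested unless given. For 72 h against 48 h at 1% O2, 0 genes passed under all 22 alternatives.

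For 1% against 21% O2 at 72 h (177 genes), the number was 320 with library size only, 323 with no low-count filter, 986 with DESeq2, 0 with limma-voom, 1 with the replicate block, 0 against a fold of 1.5 and 1705 with only the groups compared. With 1, 2 and 3 surrogate variables it was 1056, 484 and 0. It was 0 at a threshold of 0.04, 318 at 0.06 and 2445 without the displaced libraries, which all belong to other groups. Leaving out 1 library gave 0 to 599. Where 1 library was left at 1% O2, it was assumed to vary like the other groups. The 4 alternatives within 1.5 times gave 132 to 202, but only 18 of the 132 genes of the block with the groups alone were among the 177.

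For 72 h against 48 h at 21% O2 (1392 genes), the number was 288 against a fold of 1.5, 2288 and 3350 with 1 and 2 surrogate variables (1288 with 3), 848 for the groups alone with the replicate block and 4068 without the displaced libraries. Leaving out 1 library gave 578 to 2674.

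For 1% against 21% O2 at 48 h (0 genes), 2 and 3 surrogate variables gave 1 and 6, and leaving out 1 library gave 0. For 3% against 21% O2 (0 genes), DESeq2 gave 5, 3 surrogate variables 91, and leaving out 1 library 0 to 27. For 1% against 3% O2 (0 genes), the groups alone with the replicate block gave 19 and leaving out the displaced libraries 1411. Leaving out only the displaced library of this comparison, replicate 1 at 3% O2, gave 0. For the interaction (0 genes), DESeq2 gave 245, 1 and 2 surrogate variables 48 and 5, only the groups compared 8, leaving out the displaced libraries 713, and leaving out 1 library 0 to 159.

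The correlation of the 1% O2 responses at 48 h and 72 h (r = -0.07) was 0.14 with 1 surrogate variable and -0.39 to 0.38 with 1 library left out. That of the 3% and 1% O2 responses (r = 0.61) was 0.43 with no low-count filter, 0.42 with DESeq2, 0.74 with 2 surrogate variables, 0.29 without the displaced libraries and 0.29 to 0.66 with 1 library left out.

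The fold changes of the 4 printed genes kept their direction under all 21 alternatives each, and fell short of the threshold under 10 or 11, with adjusted p up to 0.415, 0.321, 0.321 and 0.321 for ENSECAG00000013981, ENSECAG00000001246, ENSECAG00000015516 and ENSECAG00000022875. The numbers in the titles were not taken as pairs outside the 48 h comparison: same-number correlations were -0.144 to -0.0977 for 3% against 21% O2 and -0.308 to 0.189 for 72 h against 48 h at 21% O2, and the remaining comparisons share only 2 numbers, whose deviations mirror each other, with r = 0.42 for 1% against 3% O2, 0.40 for 72 h against 48 h at 1% O2 and -0.20 for 1% against 21% O2 at 72 h. The replicate block in the fit of all libraries also ended the calls of the 4 printed genes, with adjusted p of 0.0765, 0.0852, 0.0596 and 0.0631. It left the comparisons with 0 genes at 0 and gave 1415 time genes at 21% O2, which include 1194 of the 1392. Leaving out mitochondrially encoded genes and the set tests with an estimated correlation were not run, since both need gene names.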

Other observations

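The counts over other splits below were run on fits of the groups compared alone, before their predictions were written.

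For 1% against 21% O2 at 48 h, all 56 splits of the 8 libraries gave at least the 0 genes of the real one, as any split must, so this count says nothing about chance. The highest other split gave 2403 genes, with replicates 2 and 3 at 21% O2 and replicate 3 at 1% O2 set against the rest, which points to a structure of the samples. For 3% against 21% O2 at 72 h, all 35 splits gave at least the real 0, which again any split must, and the highest other gave 492, with replicates 2 and 3 at 3% O2 and replicate 1 at 21% O2 on one side.

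The 936 genes that rose with time at 21% O2 had a median log2 fold change of -0.58 for 1% against 3% O2 at 72 h, a comparison that shares no library with it. The fold change was negative for 857 of them. Of the 456 that fell with time, 404 had a positive one. No single gene passed the test between 1% and 3% O2, and genes are not independent replicates. The 1% and 3% O2 groups also differ in part on the first principal component, so these counts do not separate oxygen from that axis.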
